A study of Oryza glaberrima with 6 samples.

How the data were processed

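Total RNA was extracted with TRIzol from leaf, root and panicle of Oryza glaberrima CG14, per the labels' protocols. The authors made the sRNA libraries by a published small RNA library protocol and the mRNA libraries with an Illumina mRNA-Seq kit. Each deposited file lists distinct sequences with the number of reads of each, so its values are raw counts with no normalization. That the values are counts was read from the files, which have no header: they are whole numbers from 1, each beside 1 distinct sequence, with a different total in each library. Trimming, length limits, any removal of structural RNA and the tools used by the authors are not given in the sources used here. Reads of 18 to 34 nt were present in the sRNA files and of 18 to 42 nt in the mRNA files. No alignment or gene assignment was used here. No reference genome or transcripts were at hand, and a table of gene symbols without sequence could not be used.

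The 6 libraries were grouped by organ and kind, 1 library per group. The pairs compared were panicle over leaf, root over leaf and panicle over root. No test between organs was run. Shares carry exact Clopper-Pearson binomial 95% intervals, abundances carry exact Poisson intervals, and ratios of 2 libraries carry the conditional binomial interval. The comparisons, their thresholds and the rule for naming items were set before the data were examined. Where a reference sequence was needed and absent, a replacement was set later, as stated for each.

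sRNA reads were counted by length and by first base, as reads and as distinct tags. For miRNA families, tags of 20 to 22 nt were matched to a hand-written list of 67 mature rice and grass sequences in 34 families, tasiR-ARF included. The list is incomplete and was not checked against a database. The start could be shifted by at most 1 nt, 1 mismatch was allowed, and tags that fitted 2 families equally well were left out. Family counts were divided by all sRNA reads of the library and given per 1000000 reads (rpm). Families with at least 100 reads in the higher library were compared. The rule named the 10 families highest in any library, the 5 largest ratios each way per comparison and the 3 most abundant tags of each library. Items outside the rule are marked as chosen after their values were seen. Fragments of rRNA and tRNA were counted with a hand-written list of 17 sequences and at most 1 mismatch, and part of that list was written after the most abundant tags had been seen. Overlap between organs was counted at full depth and after thinning to the smallest library.

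For mRNA, reads of 42 nt with no ambiguous base and no adapter were kept, which were 29399739 reads in leaf, 31515738 in root and 32446672 in panicle, or 94.2%, 94.1% and 94.4%. The adapter filter was chosen after the data were seen. It looked for GATCGGAAGAGC or GTTCAGCAGGAATGCCG. In place of genes, the first 32 nt of each read were counted as a read start, and starts with at least 200 counts in the higher library and a 4-fold ratio were counted, with a prior of 0.5 rpm. In place of gene lists, reads were translated in 6 frames and matched exactly to windows of 10 amino acids from 28 sets of conserved proteins. That protein list was written from general knowledge before its counts were seen, and sets with at least 20 reads were compared. In place of target gene lists, reads were searched on both strands for sites complementary to 20 positions of each miRNA, with a penalty of 1 per mismatch and 0.5 per G:U pair, none at positions 10 and 11, and a sum of at most 2. A read could count for more than 1 family. Background came from 10 shuffles of each miRNA.

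The alternatives tried were distinct tags in place of reads, other mismatch limits, lengths and denominators for miRNAs, median-of-ratios size factors, TMM factors from edgeR, other minimum counts, priors of 0.1 and 5, starts of 25 nt, and each distinct tag counted once. Size factors and TMM factors were computed over 3978 read starts with at least 50 counts in each of the 3 libraries. TMM was first computed over starts with at least 300 counts summed over the libraries, which gave factors of 2.29 in leaf, 0.403 in root and 1.08 in panicle in place of 0.939, 0.962 and 1.11. The change was made after these factors were seen, and the first version is kept as an added alternative.

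Left out for lack of a genome were phased siRNA loci, placement of sRNAs on the genome, differences by gene, gene lists chosen by description and lists of miRNA target genes. The procedures were tested on simulated data. miRNA matching recovered 98.5% of 201 simulated tags without mismatch and 98.01% with 1, and called 0 of 1340 shuffled ones. Simulated read starts for panicle over leaf were recovered in 100% of 50 at 6-fold, 10-fold, 20-fold and 40-fold, and 0 of 99800 unchanged starts were called. The unchanged starts differed between libraries by counting error only, and those under 200 counts could not be called. The 0 therefore says nothing on false calls between the real libraries. Peptide matching found 100% of 1650 simulated reads and 0 of 1000000 random ones. The site search gave the result of a direct search for all 355 pairs. The ratio interval held the true ratio in 96.7% of 2000 simulations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.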

Results

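Small RNA (sRNA) and mRNA were sequenced from leaf, root and panicle of Oryza glaberrima, the African cultivated rice, cultivar CG14. Each organ gave 1 sRNA library and 1 mRNA library, 6 libraries in all. There were no replicates, so no test between organs was run, and each value carries a 95% counting interval where one is given. Leaves came from greenhouse plants at a stage of 4 to 5 leaves. Roots came from plants kept in liquid medium. Panicles were taken while their upper part flowered and their lower part was still closed. The sRNA libraries held 17664268 reads from leaf, 16061426 from root and 16381611 from panicle, as distinct sequences (tags) of 18 to 34 nt. These fell into 2066800 tags in leaf, 1695539 in root and 3184279 in panicle. The mRNA libraries held 31226241, 33474323 and 34373347 reads in the same order, of at most 42 nt. A count of 0, taken as at most 3 reads, allowed up to 0.170 reads per 1000000 reads (rpm) in leaf sRNA, 0.187 in root sRNA and 0.183 in panicle sRNA. In mRNA it allowed 0.102, 0.0952 and 0.0925 rpm. Intervals and these limits cover counting error only, since the reads came from PCR without molecular identifiers.

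The length profile asked which classes of sRNA each organ holds. Plant sRNAs fall mainly into a 21 nt class that includes most miRNAs and a 24 nt class linked to silencing of transposons and repeats. Both classes stood out in all 3 organs, and 24 nt was the larger one. Reads of 24 nt made up 37.6% of leaf reads (exact binomial 95% interval 37.5 to 37.6), 32.2% of root reads (32.2 to 32.2) and 38.8% of panicle reads (38.8 to 38.9). Reads of 21 nt made up 20.4%, 18.2% and 19.04%. The ratio of 24 nt to 21 nt reads was 1.84 in leaf, 1.77 in root and 2.04 in panicle. Among distinct tags the order of the organs was different, with ratios of 6.22 in leaf, 6.36 in root and 4.29 in panicle. Panicle had the largest share of 24 nt reads, although without the 10 most abundant tags leaf was slightly above it, at 45.1% against 44.9%. Its share of 24 nt tags was the smallest at 48.5%, against 56.4% in leaf and 54.8% in root. The ends of the profile differed more. Reads of 29 to 34 nt made up 13.1% of the root library, 5.95% of the leaf library and 2.07% of the panicle library. Reads of 18 to 20 nt were most frequent in panicle at 17.2%, against 11.3% in leaf and 10.9% in root.

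**Figure D1:**
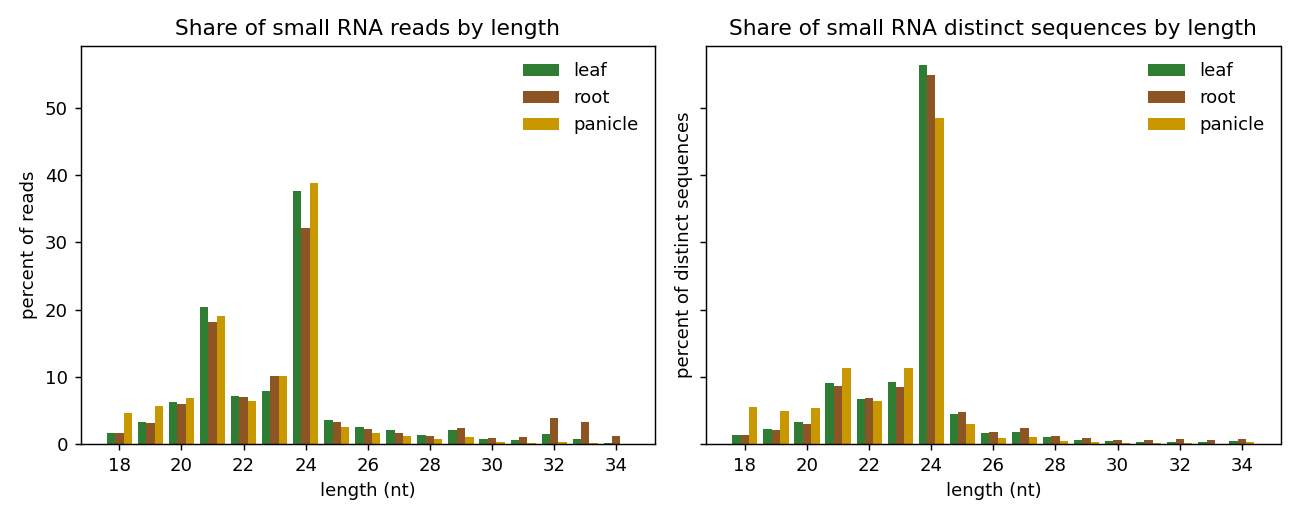
Share of sRNA reads (percent) at each length from 18 to 34 nt in leaf, root and panicle, 1 library each. The 24 nt peak held 37.6% of leaf reads, 32.2% of root reads and 38.8% of panicle reads, and root had the most reads of 29 to 34 nt.

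The first base of an sRNA is known to go with the Argonaute protein that binds it. Among 21 nt reads U was the most frequent first base in each organ, at 54.0% in leaf, 58.7% in root and 51.8% in panicle. Among 24 nt reads A was the most frequent, but less so in panicle. A began 46.1% of 24 nt reads in leaf, 51.5% in root and 38.3% in panicle. C began 8.62%, 7.08% and 13.7% of them. Each distinct tag counted once gave the same order, with A in 44.3%, 47.9% and 36.7% of 24 nt tags.

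Fragments of rRNA and tRNA led the tags that match no miRNA family, and the ranks given next leave out miRNAs. The most frequent such tag of every library was the 5′ end of 18S rRNA, TACCTGGTTGATCCTGCCAGTAG, with 25933 rpm in leaf, 55195 in root and 33910.3 in panicle. The next tags outside the miRNA families were 5′ ends of chloroplast tRNAs. Single miRNA tags were more frequent than these, such as AGAATCTTGATGATGCTGCAT of miR172 at 37001 rpm in leaf, above the 18S rRNA tag, 30932 in root and 21505 in panicle. In leaf these were GGGATTGTAGTTCAATTGGTCAGAGCACC of tRNA-Asp at 8301 rpm and AGGGCTATAGCTCAGTTCGG of tRNA-Val at 7043 rpm. In root they were a longer tRNA-Asp form, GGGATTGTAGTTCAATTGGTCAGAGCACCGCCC, at 15784 rpm and the same tRNA-Val tag at 12258 rpm. In panicle they were GGGCCTGTAGCTCAGAGGA of tRNA-Arg at 7820.05 rpm and the tRNA-Val tag at 7588 rpm. Summed over a hand-written list of 17 rRNA and tRNA sequences, which is incomplete, such fragments took 12.2% of leaf reads, 20.1% of root reads and 10.9% of panicle reads. Chloroplast tRNA fragments were the largest part in root, a non-green organ, with 10.4% of reads against 5.38% in leaf and 3.66% in panicle. The root to leaf ratio of chloroplast tRNA fragments was 1.93 (1.92 to 1.93). The members, named after their values were seen, did not all go one way. tRNA-Asp had 49292 rpm in root and 21249.7 in leaf and tRNA-Phe 23768 and 7760.2 rpm, while tRNA-His had 1854 and 2567 rpm and tRNA-Ile 2938 and 4884 rpm.

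The ratios between libraries changed with length in each class of sRNA counted. The list of rRNA and tRNA sequences is incomplete, so reads with no match can include such fragments. Among reads of 32 to 34 nt the root to leaf ratio was 3.41 for chloroplast tRNA fragments, 2.61 for nuclear tRNA fragments, 3.002 for rRNA fragments and 3.65 for reads with no match to these. Among reads of 18 to 20 nt these ratios were 1.45, 0.902, 1.14 and 0.876. The panicle to leaf ratio fell with length, from 1.17, 1.72, 1.13 and 1.59 at 18 to 20 nt to 0.233, 0.190, 0.265 and 0.299 at 32 to 34 nt.

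**Figure D2:**
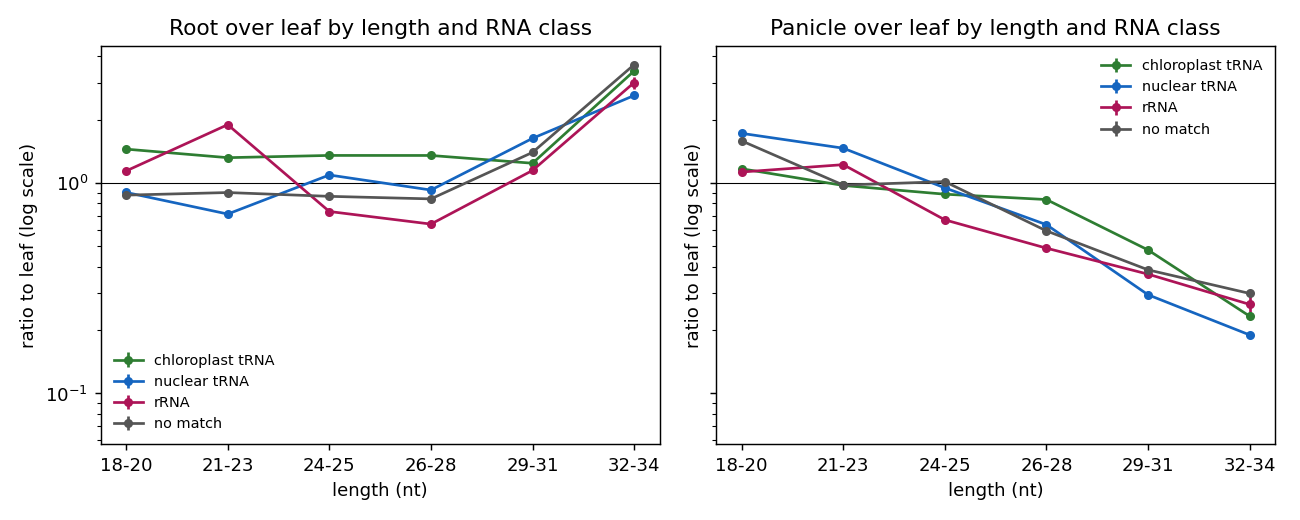
Ratio of rpm between sRNA libraries (log axis) by read length (nt), for chloroplast tRNA, nuclear tRNA, rRNA and reads with no match, with 95% counting intervals. At 32 to 34 nt all 4 classes were above 1 for root over leaf and below 1 for panicle over leaf.

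The miRNA comparison asked how abundant known families are in each organ. Conserved families control flowering phase, leaf and flower form, hormone response and nutrient uptake. The same few families led in all 3 organs, and most families differed by less than 2-fold between organs. The clearest difference was in tags assigned to miR529, which were far more abundant in panicle than in leaf or root. Nearly all of the panicle reads differed from the listed miR529 sequences. Tags matching 1 of 67 mature sequences in 34 families made up 15.3% of leaf reads, 13.7% of root reads and 11.3% of panicle reads. At least 100 reads were found for 24 families in leaf, 25 in root and 28 in panicle. The listed miR1318 and miR1432 sequences are the same but for a shift of 1 nt, so nearly all their tags tied and were left out. In leaf, root and panicle these sequences had 376, 478 and 298 reads and 285, 512 and 344 reads. Neither family is in these counts or in the family ratios below.

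The most abundant family was miR156, known for marking the juvenile phase, with 55105 rpm in leaf, 51112 in root and 40038 in panicle. It was followed by miR172, which targets AP2-type flowering regulators, with 39002, 33706 and 23515 rpm. miR167 reached 25950.1 rpm in leaf, 14889.5 in root and 13647 in panicle. miR159 was highest in root at 21335 rpm, against 11419.7 in leaf and 11503 in panicle. miR169, which targets NF-YA factors, was highest in leaf at 6221 rpm, against 2222 in root and 2539 in panicle. miR166, which targets HD-ZIP III leaf polarity factors, was highest in panicle at 7607 rpm, against 3257 in leaf and 3009 in root. miR168, which targets ARGONAUTE 1, had the same order, with 4727 rpm in panicle, 2286 in leaf and 1593 in root. For miR535 the values in leaf, root and panicle were 3066, 3977 and 3425 rpm, for miR1425 1611, 1349.6 and 1302 rpm, and for miR396 971, 958 and 1639 rpm.

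**Figure D3:**
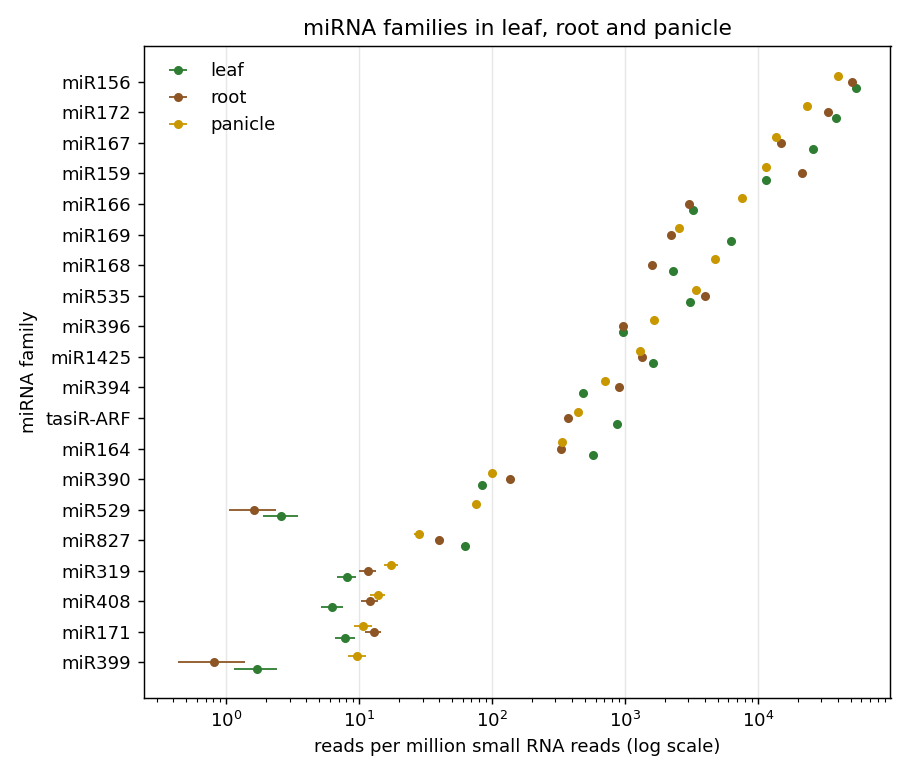
Abundance of miRNA families in rpm of all sRNA reads (log axis) in leaf, root and panicle, 1 library each, with 95% counting intervals. Most families lay close together in the 3 organs, and miR529 stood apart with 76.2 rpm in panicle against 2.60 in leaf and 1.62 in root.

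Between panicle and leaf, 7 of 28 families with at least 100 reads in the higher library were at least 2-fold higher in panicle and 2 were at least 2-fold lower. miR529, which targets SPL factors, was 29.3-fold higher (conditional binomial 95% interval 21.8 to 40.2), from 46 reads in leaf and 1249 in panicle. With exact matching its log2 ratio was 3.81 in place of 4.87. Of the 1249 panicle reads 979 were the tag AGAAGAGAGAGAGTACAGCCT, which is not in the reference list and was matched with a mismatch. The listed sequences themselves had few reads in leaf, root and panicle, 11, 0 and 4 for AGAAGAGAGAGAGTACAGCTT and 0, 0 and 2 for CTGTACCCTCTCTCTTCTTC. Exact matching allowed a shift of 1 base and so included GCTGTACCCTCTCTCTTCTTC, with 0, 0 and 162 reads. miR399, a regulator of phosphate uptake, was 5.68-fold higher (3.83 to 8.70), from 30 and 158 reads. The log2 ratio was 1.22 for miR166, 1.13 for miR408, 1.11 for miR319, 1.77 with exact matching, and 1.05 for miR168. miR162 completed the 7 with a log2 ratio of 1.07 and was chosen after its value was seen. Scaling by size factors over the families lowered log2 ratios over leaf by 0.23 for root and 0.31 for panicle. This turned the balance, with 2 families higher and 6 lower. It brought miR166, miR408, miR319, miR162 and miR168 under 2-fold, to 0.92, 0.83, 0.80, 0.77 and 0.74. miR169 had a log2 ratio of -1.29 and miR827 one of -1.15. Counted among miRNA reads without miR156 these became -0.87 and -0.73. The next families on the lower side were the trans-acting siRNA tasiR-ARF at -0.98, miR167 at -0.93 and miR164 at -0.78. With size factors these became 2-fold lower, at -1.28, -1.23 and -1.08, as did miR172, from -0.73 to -1.03.

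Between root and leaf, none of 25 families was at least 2-fold higher in root and 2 were at least 2-fold lower. The count of 0 depended on the denominator. Without rRNA and tRNA fragments, which took more of the root reads, 3 families were 2-fold higher, miR408 at 1.07, miR159 at 1.04 and miR394 at 1.02. The largest log2 ratios were 0.94 for miR408, 0.90 for miR159, 0.89 for miR394, 0.72 for miR171 and 0.70 for miR390. Those of miR408 and miR394 rested on 111 and 8598 reads in leaf. On the lower side they were -1.49 for miR169, -1.21 for tasiR-ARF, -0.81 for miR164, -0.80 for miR167 and -0.64 for miR827. With exact matching the tasiR-ARF ratio became -0.71. With size factors miR164 and miR167 also became 2-fold lower, at -1.04 and -1.03.

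Between panicle and root, 4 of 28 families were at least 2-fold higher in panicle and none was 2-fold lower, although miR159 was at -1.05 without rRNA and tRNA fragments. miR529 was 47.1-fold higher in panicle (31.99 to 72.4) and miR399 was 11.9-fold higher (6.77 to 22.9), the latter from 13 reads in root. The log2 ratio was 1.57 for miR168, 1.34 for miR166 and 0.77 for miR396. On the lower side it was -0.89 for miR159, -0.52 for miR172, -0.50 for miR827, -0.45 for miR390 and -0.35 for miR156.

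Single sequences within families, chosen after their values were seen, did not always follow the family. The miR166 form TCGGACCAGGCTTCATTCCTC had 285 rpm in leaf, 235 in root and 1752 in panicle, while TCGGACCAGGCTTCATTCCCC reached 1567, 1579.8 and 3351 rpm. miR2118 and miR2275 are known triggers of phased siRNAs in grass inflorescences. No read matched the 2 miR2118 sequences searched in any of the 3 libraries, and tags matching the 1 miR2275 sequence had 7 reads in leaf, 7 in root and 6 in panicle. The hand-written miRNA list is incomplete, so members that differ more from these sequences were not searched. Most miR820 reads were 24 nt long, outside the 20 to 22 nt used for families. The most abundant 24 nt form, TCGGCCTCGTGGATGGACCAGGAG, had 5235 rpm in leaf, 5639 in root and 2518 in panicle. A form with the substitution G11A, counted from 1 at the 5′ end, had 3.17 rpm in leaf, 22.8 in root and 2349 in panicle.

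The overlap of sequences asked how much of the sRNA population the organs share. Few sequences were shared, but they carried most of the reads. Of 5174207 distinct sRNA tags, 479992 were found in all 3 libraries, which was 9.28% of tags and 72.1% of reads. Tags of a single library made up 75.02% of tags and 16.5% of reads. Thinning each library to 16061426 reads left the shared part at 9.26% of tags and 71.9% of reads. Panicle had the most sRNA of its own. After thinning, tags seen in 1 library alone held 34.99% of 24 nt reads in panicle, 20.4% in leaf and 15.1% in root. For 21 nt reads these shares were 18.3%, 5.66% and 4.06%.

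A large group of abundant tags was nearly restricted to panicle, and this group was chosen after its values were seen. Tags with at least 200 reads in one library and under 0.1 of that abundance in both others numbered 987 in panicle, 6 in root and 0 in leaf. The panicle group held 631244 reads, and 250 of its tags were absent from both other libraries. Of the 987 tags 683 were 24 nt long, or 69.2% (66.2 to 72.1), against 39.1% (37.6 to 40.6) of all panicle tags with at least 200 reads. A began 22.1% of these 24 nt tags and C began 23.1%. Among the 902 other abundant 24 nt tags of panicle A began 45.5% and C began 6.65%. Tags were not independent, since 327 of the 683 shared a stretch of 16 bases with another tag, as did 498 of the 902. The intervals over tags do not allow for this.

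The mRNA comparison asked how gene expression differs between the organs. No genome or transcript sequence was used here, so reads were compared by their own sequence with no gene name, and then by the proteins they encode. Of 42849756 distinct 42 nt tags, 3.85% were in all 3 libraries and held 32.6% of reads. This low share of tags rested on tags seen once, since with at least 2 reads per tag it was 16.4%, close to the 16.7% of sRNA tags counted that way. Thinned to 29399739 reads per library, the share of reads in tags of 1 library alone was 41.6% in leaf, 53.3% in root and 51.3% in panicle.

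Read starts of 32 nt with at least 200 counts in the higher library differed most often between root and leaf. Between panicle and leaf 6991 starts were compared, of which 899 were at least 4-fold higher in panicle and 2783 at least 4-fold lower. Between root and leaf 7109 were compared, with 1018 higher in root and 4807 lower. Between panicle and root 3953 were compared, with 1385 higher in panicle and 878 lower. Several starts can come from 1 transcript, so these are not counts of genes. The counts depend strongly on the minimum count and on the scaling. With TMM factors over starts with 300 summed counts, 1227 were higher and 1100 lower in panicle over leaf, and 928 higher and 1374 lower in panicle over root, so the balance turned in both.

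Reads encoding conserved stretches of 28 well-known proteins or protein groups showed which functions differed. Photosynthesis transcripts were highest in leaf, floral regulators and pollen-type proteins in panicle, and non-symbiotic hemoglobin in root. Transcripts for the small subunit of RuBisCO had 9292 rpm in leaf, 189 in root and 1826 in panicle, and were 49.3-fold lower in root than in leaf (48.0 to 50.6). Light-harvesting proteins fell by 3.77 on the log2 scale from leaf to root, and by 1.63 from leaf to panicle. The chloroplast-encoded large subunit of RuBisCO and photosystem II D1 had log2 ratios of -5.87 and -5.76 for root over leaf, and of -2.24 and -3.15 for panicle over leaf. These came from few reads, 5991 and 5711 in leaf and 110 and 113 in root. With each distinct tag counted once, the log2 ratios of root over leaf were -3.79 for the RuBisCO small subunit in place of -5.62, -2.50 for light-harvesting proteins, -4.59 for the RuBisCO large subunit and -4.43 for photosystem II D1. Under the same count those of panicle over leaf were -1.64 for the small subunit, -1.58 for the large subunit and -2.23 for D1. With TMM factors over starts with 300 summed counts, light-harvesting proteins were under 2-fold in panicle over leaf, at -0.55.

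Floral MADS-box transcripts marked the panicle. The SEP/AP1 type had 264 rpm in panicle, 16.9 in leaf and 11.2 in root. The log2 ratios of panicle over leaf were 3.97 for the SEP/AP1 type, 4.26 for the AG type, 4.30 for the AP3 type and 3.59 for the PI type. A pollen-type beta-expansin was 19.97-fold higher in panicle than in leaf (17.9 to 22.3) and profilin was 6.11-fold higher (5.76 to 6.50). With each distinct tag counted once, the log2 ratios of panicle over leaf were 2.48 for beta-expansin in place of 4.32, 1.92 for profilin in place of 2.61, and 2.50, 3.14, 2.83 and 2.23 for the SEP/AP1, AG, AP3 and PI types. Non-symbiotic hemoglobin had 175 rpm in root, 17.4 in leaf and 0.925 in panicle. It was 10.03-fold higher in root than in leaf (9.16 to 10.996), a log2 ratio of 3.33 that was 2.03 with each distinct tag counted once. Alcohol dehydrogenase 1 was highest in panicle instead, with 284 rpm against 118 in root and 61.1 in leaf. The panicle over root ratio of alcohol dehydrogenase 1 changed direction under one added scaling, to -0.16 on the log2 scale.

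Transcripts tied to cell division were higher in root than in leaf, and so were most housekeeping ones. The log2 ratios were 2.23 for histone H3.1, 1.61 for PCNA and 1.40 for histone H4, the last 0.86 with each distinct tag counted once. They were 1.56 for alpha-tubulin, 1.54 for calmodulin, 1.52 for ribosomal protein L40, 1.26 for actin, 1.19 for HSP70 and 1.01 for elongation factor 1-alpha, and each of these 6 came under 2-fold with each distinct tag counted once. For panicle over leaf, PCNA and histone H4 had log2 ratios of 1.43 and 1.06, the latter 0.84 with size factors. Histone H3.3 changed less, with 1.43-fold (1.35 to 1.51) between root and leaf. PIP aquaporins had 732 rpm in root, 415 in leaf and 297 in panicle. In all, 13 of 28 sets were at least 2-fold higher in panicle than in leaf (9 with size factors) and 5 lower. Between root and leaf 11 were higher in root and 4 lower, and between panicle and root 11 were higher in panicle and 4 lower. With each distinct tag counted once, 8 were higher in panicle than in leaf and 3 in root than in leaf. With TMM factors over starts with 300 summed counts these 2 counts were 22 and 24. Size factors over 3978 read starts lowered log2 ratios over leaf by 0.03 for root and 0.23 for panicle. With TMM factors over starts with 300 summed counts, all log2 ratios were 1.08 higher for panicle over leaf, 2.50 higher for root over leaf and 1.43 lower for panicle over root. The reads cannot tell gene copies apart.

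**Figure D4:**
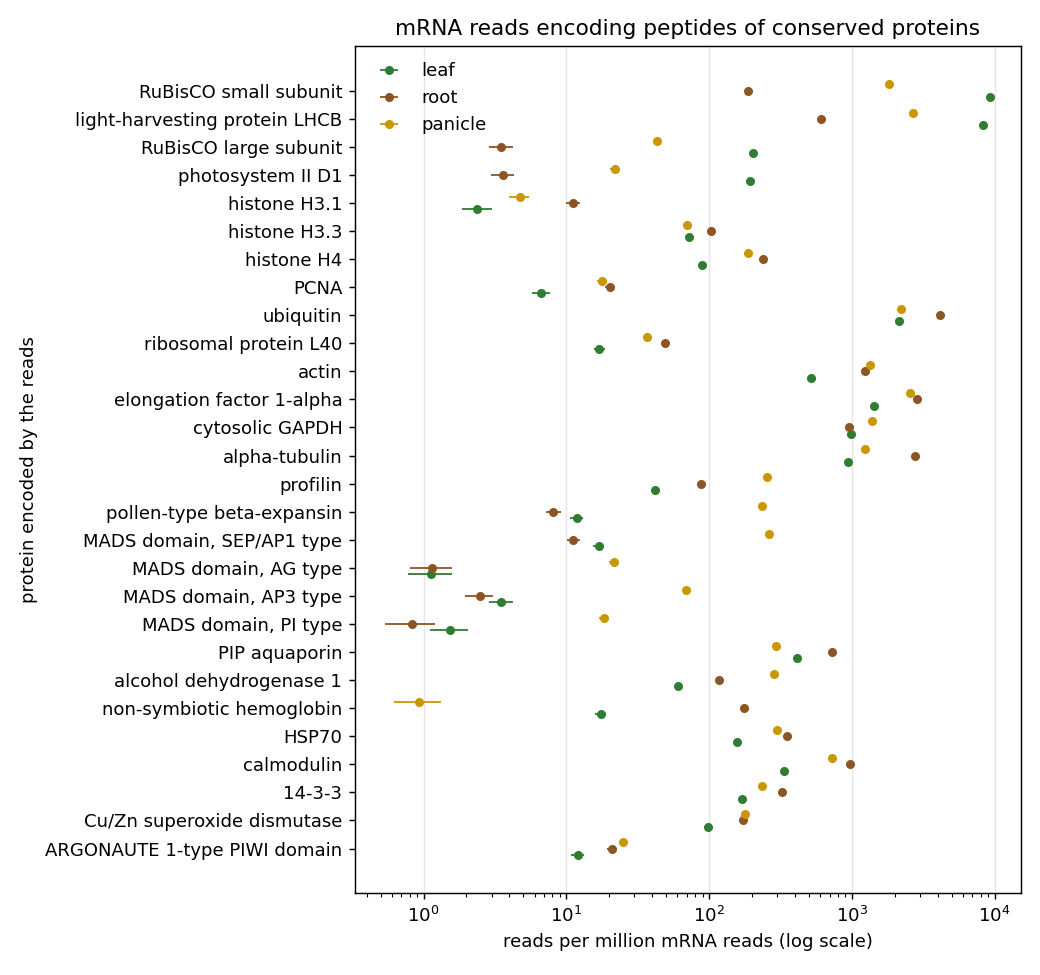
Reads encoding conserved stretches of each protein set, in rpm of kept mRNA reads (log axis), in leaf, root and panicle, 1 library each, with 95% counting intervals. The RuBisCO small subunit reached 9292 rpm in leaf and 189 in root, and the SEP/AP1 type reached 264 rpm in panicle and 16.9 in leaf.

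The pairing of sRNA and mRNA libraries allowed miRNAs to be set beside sequences they could bind. mRNA reads that held a site complementary to a miRNA, at a penalty of at most 2, numbered 1290 in leaf, 2123 in root and 1642 in panicle. Both strands were searched, so a read of a miRNA precursor, which holds the miRNA itself, also counts as a site. Such reads cannot be told apart from reads of a target. Shuffled miRNA sequences gave means of 293, 316 and 378 reads, so the background was not small. The site sequences named next were chosen after their values were seen. The site GTGCTCTCTCTCTTCTGTCA, complementary to miR156, had 18 reads in leaf, 43 in root and 53 in panicle. miR156 itself was lowest in panicle. The miR172 site TGCAGCATCATCAGGATTCT had 127, 225 and 39 reads, and both this site and miR172 were lowest in panicle. The miR398 site AGGGGTCGCCTGAGAACACA had 19, 76 and 138 reads, while miR398 itself had only 30, 32 and 32 reads. Of 21 families with enough site reads, 12 had opposite signs of the miRNA and site log2 ratios in each of the 3 comparisons, which was 57.1% (34.02 to 78.2). Among families whose site ratio had an interval that excluded 1, these were 8 of 17 for panicle over leaf, 8 of 15 for root over leaf and 6 of 11 for panicle over root. The background differed by family. Over the 3 libraries site reads were 66 against a shuffled mean of 66.0 for miR171 and 167 against 117 for miR529. For miR172 they were 571 against 4.7. Signs of families near their background can come from unrelated sequences. No minimum was set for miRNA reads, so some signs rest on very few. miR1318 entered panicle over leaf with 1 read in each library, and miR1432 had 7, 3 and 2 reads in leaf, root and panicle. The listed miR1432 sequence had 285, 512 and 344 reads, which fitted miR1318 equally well and were left out.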

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

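A pair of signals lay outside the comparisons and above the limit that a count of 0 allows. Adapter-derived reads made up 1.20% of the leaf mRNA library, 1.06% of the root mRNA library and 0.899% of the panicle mRNA library, and were left out of the mRNA counts. The 24 nt miR820 form with the substitution G11A was outside the lengths used for families, at 3.17 rpm in leaf, 22.8 rpm in root and 2349 rpm in panicle. All tests in this part were chosen after the results were seen, except the search of panicle tags in mRNA reads, which was set before.

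A group of 24 nt tags was abundant in panicle and rare in leaf and root. Depth was argued against by the read numbers, since leaf was deeper than panicle, with 17664268 against 16381611 reads. Thinning tested little, because the libraries were close in depth. After it 34.99% of all panicle 24 nt reads lay in tags of that library alone, against 20.4% in leaf. These shares are not limited to the group. RNA breakdown, or RNA of an organism with no 24 nt class, would spread such tags over lengths. Among the 987 tags picked by abundance the 24 nt share was 69.2% (66.2 to 72.1), above the 39.1% of all abundant panicle tags. This argued against these sources for most of the 987 tags. The share is part of the pattern that prompted the test, so it adds no separate support. Many of these tags share bases and are not independent, which the intervals over tags given here do not allow for. Pieces of polyadenylated panicle transcripts would occur more often in panicle mRNA reads than the other abundant tags. The reverse was found, with 5.12% (3.59 to 7.06) of the group's 24 nt tags against 38.4% (35.2 to 41.6) of the others. The same gap held in leaf mRNA, 3.81% against 33.4%, and in root mRNA, 3.07% against 34.7%. It is therefore not particular to panicle transcripts and cannot decide on this source. Within the group the share was highest in panicle mRNA, with overlapping intervals. The look-up used stretches of 20 nt on either strand. Production of these sRNAs in flowering organs stays open as a hypothesis, as does a difference in growth conditions or library making, because each organ has 1 library.

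Chloroplast tRNA fragments as a class and long reads were highest in the root sRNA library, although tRNA-His and tRNA-Ile fragments were higher in leaf. Leaf RNA in the root sample was argued against as the source of the excess, since a mixture cannot exceed its source and the root to leaf ratio was 1.93 (1.92 to 1.93). This holds only where both libraries capture a length alike, and the pooled ratio includes long reads. Fragments of 18 to 20 nt were also more frequent in root, with a ratio of 1.45. The class covers only listed chloroplast tRNAs, and part of the list was written after the most abundant tags were seen. A wider size selection of the root library could account for the reads of 32 to 34 nt. Reads with no rRNA or tRNA match had a ratio of 3.65 there, close to the 3.41 of chloroplast tRNA fragments. The list of these RNAs is incomplete, so reads with no match can be fragments of the same kind. They are thus no separate control for size selection. It does not account for all the chloroplast tRNA fragments, since those of 18 to 20 nt had a ratio of 1.45. A biological difference between leaf and root plastids stays open and was not tested.

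Every sRNA tag with at least 1000 leaf reads was also present in root. This was not particular to root, since all were present in panicle too, where the lowest ratio to leaf was 0.0851. In reverse, of 592 such panicle tags 57 had no leaf read and 3 had no root read. As the main source of these 738 tags in root, carry-over of leaf RNA or reads would put most of them near one low ratio. Only 0.271% lay within 1.5 times of the lowest root to leaf ratio of 0.126. For carry-over of root into leaf, 1.77% of 623 abundant root tags lay near the lowest leaf to root ratio. Carry-over as the main source was thus argued against both ways. Carry-over on top of an organ's own sRNAs would only set a lowest ratio, so these shares cannot test it. Among tags with at least 200 reads, ratios went down to 0.106 for root to leaf at 21 nt and 0.0941 for leaf to root at 24 nt. A carry-over no larger than these stays open, as does production of the same sRNAs in both organs.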

How the results depend on the processing

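No paired analysis was possible because each organ gave 1 library of each kind. Depth limited families with few reads, such as miR399 with 13 reads in root. Among 58 ratios of the 20 miRNA families chosen by rank, which leave out miR162 and the other families compared, no direction was called and then reversed in 403 alternative values, although 20 of them changed sign for families near 0, and 7 of 98 values of 2-fold families fell under 2-fold. The largest move was that of miR529 in panicle over leaf, with a log2 ratio of 3.81 under exact matching in place of 4.87. Among 84 protein set ratios 1 called value of 336 reversed, and 30 of 192 values of 2-fold sets fell under 2-fold. Called or not, 24 of the 336 changed sign. Among 63 site ratios 4 called values of 96 reversed, and 18 of 45 values of 2-fold ratios fell under 2-fold. Called or not, 24 of the 96 changed sign. Alternatives set beforehand but not run for lack of a genome were sRNAs with a genome match only, all those of phased siRNA loci and of genome placement, and for gene lists the 25 nt start and the minimum per member. Penalties other than 2, TMM over starts with 300 summed counts, scaling and distinct tags for protein sets, leaving out rRNA and tRNA fragments for miRNAs, and thinning of mRNA for the search of sRNA tags were added after seeing the data. The list behind the removal of these fragments from the size profile was also partly written then. Except where the construction of an alternative shows it, the cause of a change was not tested.

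As distinct tags, the 21 nt share was 9.06% in leaf, 8.62% in root and 11.3% in panicle, and the 24 nt share was 56.4%, 54.8% and 48.5%. Without the 10 most abundant tags these shares were 13.6%, 12.6% and 14.9% at 21 nt, and 45.1%, 40.8% and 44.9% at 24 nt. Without rRNA and tRNA fragments they were 22.7%, 22.2% and 20.8%, and 42.3%, 39.8% and 43.2%. As distinct tags, U began 38.4%, 42.01% and 31.8% at 21 nt, and A began 44.3%, 47.9% and 36.7% at 24 nt.

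With size factors, 2 families were 2-fold higher and 6 lower in panicle over leaf, and 4 were lower in root over leaf. Among miRNA reads without miR156, 0 were lower in panicle over leaf and 3 higher in root over leaf. Per reads of 20 to 24 nt, 2 were higher in root over leaf and 1 lower in panicle over root. Without rRNA and tRNA fragments these were 3 and 1. With exact matching 1 was lower in root over leaf. With at least 2 reads per tag, the part shared by all 3 organs was 16.7% of sRNA tags and 75.6% of reads, and 16.4% of mRNA tags and 50.2% of reads.

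For read starts, the values here are higher and lower counts for panicle over leaf, root over leaf and panicle over root. A minimum of 50 counts gave 6329 and 9596, 5271 and 25271, and 9596 and 6479. No minimum gave 6385 and 9781, 5328 and 26829, and 9660 and 6664. A prior of 5 gave 62 and 430, 56 and 1320, and 112 and 90. Each distinct tag counted once gave 0 and 2, 0 and 3, and 0 and 0. Few distinct tags can share a start of 32 nt, so this outcome is fixed by construction and says nothing on how stable the counts are. TMM over starts with 300 summed counts gave 1227 and 1100, 1763 and 3166, and 928 and 1374, so that the larger side changed in panicle over leaf and in panicle over root. Starts of 25 nt, a prior of 0.1, size factors and TMM over 3978 starts left all 6 counts within 1.5 times.

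For protein sets, each distinct tag counted once kept the direction of all 48 ratios of at least 2-fold, but brought 47 closer to 0, moved 33 by over 1.5 times and left 32 at 2-fold or more. Distinct tags rise less than reads where reads are many, so part of this move is fixed by construction. The RuBisCO small subunit had 273187 leaf reads in 14073 distinct tags and 5942 root reads in 1458. How large that part is was not tested. Each distinct tag counted once gave 8 higher in panicle over leaf, 3 higher in root over leaf and 2 lower in panicle over root. TMM over starts with 300 summed counts gave 22, 24 and 16, and reversed alcohol dehydrogenase 1 in panicle over root to -0.16. A penalty of up to 3 reversed the site log2 ratios of miR397 to 0.090 in panicle over leaf and 1.33 in root over leaf, of miR1432 to -0.33 in root over leaf and of miR529 to -0.080 in panicle over root. At that penalty site reads were only 1.86, 2.42 and 1.96 times those of shuffled miRNAs in leaf, root and panicle.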

Other observations

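Most housekeeping and stress proteins had more reads in root than in leaf, except cytosolic GAPDH, whose root over leaf ratio was 0.959 (0.944 to 0.975) but above 1 with TMM factors over starts with 300 summed counts. Ubiquitin transcripts had 2129.5 rpm in leaf, 4162 in root and 2205 in panicle. Ribosomal protein L40 had 17.1, 48.9 and 37.05 rpm, and elongation factor 1-alpha 1427, 2870.1 and 2577 rpm. Actin transcripts had 519 rpm in leaf, 1247 in root and 1349 in panicle, and alpha-tubulin 941, 2772 and 1242 rpm. Cytosolic GAPDH had 993, 952 and 1389.9 rpm. HSP70 transcripts had 156, 354 and 301 rpm, and calmodulin 335, 976 and 724 rpm. Transcripts for ARGONAUTE 1-type proteins, which miR168 is known to target, had 12.01 rpm in leaf, 20.9 in root and 25.1 in panicle.

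Reads over sites complementary to miR408, chosen after the values were seen, numbered 26 in leaf, 100 in root and 26 in panicle. Reads of the miR408 precursor may be among them, since both strands were searched. The size of the difference depended on the penalty. At a penalty of up to 1 the log2 ratio was 1.08 in place of 1.84 for root over leaf, and -4.47 in place of -1.99 for panicle over root.

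A hypothesis set before its result was that sRNA sequences of each organ occur more often in the mRNA reads of that organ. The data argued against it for leaf and root, but not for panicle, since panicle mRNA held the most for all 3 organs. Not all tags were searched. At 24 nt the search covered 781818 of 1164879 tags in leaf, 568455 of 929525 in root and 787981 of 1545169 in panicle. The look-up used stretches of 20 nt on either strand, and the shares below are of the tags searched. For leaf, 6.54% (6.49 to 6.60) of 24 nt tags occurred in leaf mRNA reads, against 6.97% in root mRNA and 8.03% in panicle mRNA. For root, 7.31% of 24 nt tags occurred in root mRNA and 8.43% in panicle mRNA. For panicle, 7.65% occurred in panicle mRNA, against 6.13% in leaf mRNA and 6.68% in root mRNA. Depth did not explain this alone, although the mRNA libraries held 12696358, 18203164 and 19199682 distinct tags in leaf, root and panicle. With each cut to 12696358 distinct tags, leaf 24 nt tags occurred at 6.54% in leaf mRNA, 6.05% in root mRNA and 6.84% (6.78 to 6.89) in panicle mRNA, so leaf and root changed order. Root 24 nt tags then occurred at 6.35% in root mRNA and 7.18% in panicle mRNA, and panicle 24 nt tags at 6.45% in panicle mRNA and 6.13% in leaf mRNA. Reversed sequences gave at most 0.171%. Tags of 21 nt from leaf occurred more often, at 22.7%, 21.8% and 24.2%, but with equal distinct tags leaf mRNA held the most of them, at 22.7% against 20.1% in root mRNA and 22.1% in panicle mRNA.

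A hypothesis formed after values had been seen was that reads over sites move against their miRNA family between organs. Opposite signs were found in 57.1% of 21 families (34.02 to 78.2) in each comparison, an interval that includes an even split, so the data could not decide it. Among families whose site ratio had an interval that excluded 1, signs were opposite in 8 of 17 for panicle over leaf, 8 of 15 for root over leaf and 6 of 11 for panicle over root. Some signs rest on few miRNA reads, such as the 7, 3 and 2 of miR1432 in leaf, root and panicle, since no minimum was set for them. Site reads can also include reads of miRNA precursors, and in some families they were near the shuffled background.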
